A study of Homo sapiens with 3 samples.

How the data were processed

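Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on primary human endometrial stromal cells that were being driven to decidualize, the differentiation that stromal cells of the uterine lining undergo under progesterone and cAMP. Per the labels' protocols, the cells were used at passages 2 to 4 and treated with 10 nM 17β-estradiol, 100 nM of the progestin medroxyprogesterone acetate and 1 mM cAMP in medium with 2% stripped serum. Sonicated chromatin was precipitated with an antibody to the forkhead transcription factor FOXO1 or to RNA polymerase II (RNA PolII), and an input library of DNA without precipitation was also made. Fragments of 200 to 300 bp were selected on a gel and amplified for 18 cycles before sequencing on a HiSeq instrument. There were 3 libraries, 1 per antibody and 1 input, so no value below has a replicate, and the number of donors or cultures behind each library is not given in the sources used here. The grouping followed the antibody named in the labels. The input library is not analysed here as such, since the values used come from the 2 peak lists.

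Each peak list gave 1 interval per line, with a chromosome, a start, an end, a whole-number score and a running name, and no header. Per the submitters' processing notes, BWA and SICER were used with the genome build GRCh37.p2. The notes used here give no version, role, setting or threshold for either tool, and how the input entered peak calling is not given in the sources used here. The deposited score is not defined in the sources used here, so it was used only to rank or filter intervals within 1 list, and scores of the 2 antibodies were never set against each other. Whether it is a fold over input, which the planned ranking assumed, is not known. The intervals of the 2 deposited lists were built differently. Every RNA PolII start was a multiple of 200 bp and neighbouring intervals lay at least 800 bp apart, so that broad enriched stretches were joined; they are called domains here. Only 0.53% of FOXO1 starts were multiples of 200 bp, and neighbouring FOXO1 intervals lay as close as 1 bp apart. The read depth of the libraries is unknown from these lists, so no detection limit can be given.

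Intervals on chromosomes 1 to 22 and X were used. Coordinates are those of the files on GRCh37; whether the first base counts as 0 or 1 is not stated, so printed positions may be off by 1 bp. Starts and ends were treated as inclusive. No genome sequence was used here, and the gene table used here is on another build, so no interval was assigned to a gene. For this reason 4 analyses planned before the data were examined were not run: position relative to genes, genes with a peak, occupancy of preset gene lists, and sequence motifs. The rule for named items was also fixed before the data were examined. It was written for genes ranked by fold over input and was applied to intervals ranked by score: the 10 highest-scoring intervals of each antibody, and the 10 overlapping pairs with the best worse-of-both rank. Its minimum of reads and its preset genes could not be applied. Regions named outside this rule are marked as chosen after their values were seen.

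The overlap of the lists was counted with a minimum of 1 bp. It was set against 1000 random placements of the FOXO1 intervals, each kept at its own width and on its own chromosome, within the span from the first to the last interval of either list. The same placements served for the position of FOXO1 midpoints relative to RNA PolII domains, for domains grouped by width, and for FOXO1 clusters, defined as runs of at least 5 peaks with at most 10 kb between neighbours. These placement tests describe these libraries and do not replace replicates. Wilson intervals of 95% are given for shares of peaks; they cover counting error only and treat peaks as independent, which neighbouring peaks are not. Scores of FOXO1 peaks with and without RNA PolII were compared by a two-sided permutation test with 100000 resamples, which also treats peaks as independent. Correlations across the 22 autosomes were tested by permutation in the same number, with Benjamini-Hochberg adjustment over 7 relations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

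The overlap, score, cluster and distance calculations were tested on simulated data first. On 26620 simulated peaks with 5% moved into RNA PolII domains, the true ratio to random placement was 1.86 and 1.85 was recovered; with none moved, 0.97 was recovered against a true 1. A score difference of 2 was recovered as 2, and 50 planted clusters as 50. The distance of 200 simulated midpoints to the nearest domain matched a search of all domains in 200 of 200 cases. Alternatives to the main settings listed before the data were examined were a higher score minimum for interval numbers and overlap, merging of intervals within 1 kb, another overlap rule and autosomes only. For distance bands, domain widths, clusters and autosome densities, the higher score minimum was added after seeing the data. Added after seeing the data were placements kept out of long peak-free spans, FOXO1 peaks moved by fixed ranges of distance, separately or together by chromosome, lists without the highest scores, domains of limited width, strata of peak width, scores rotated along the genome, other cluster distances, lists without single chromosomes, and random placement as the comparison for RNA PolII scores, also within 10 classes of domain width. A filter on p or q values could not be run because the lists hold none.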

Results

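FOXO1 is a forkhead transcription factor that accumulates in the nuclei of decidualizing stromal cells, and RNA PolII marks chromatin being transcribed. The series title places the work in a study of how FOXO1 is needed for progesterone receptor binding at IRF4, a transcription factor gene. The ChIP-seq data addressed where FOXO1 sat in the chromatin of decidualizing endometrial stromal cells and how those sites lay relative to transcribed stretches. Deposited lists were available for 1 FOXO1 library and 1 RNA PolII library. There were no replicates, and the lists do not give the read depth.

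The FOXO1 list held many short intervals, whereas the RNA PolII list held fewer and much broader domains; the lists were built differently, and the part of this due to interval calling was not separated. The FOXO1 list held 26620 intervals with a median width of 828 bp (interquartile range 699 to 997 bp), which together covered 23.6 Mb or 0.80% of the span examined. The RNA PolII list held 13460 domains with a median width of 7600 bp (interquartile range 4200 to 13600 bp), which covered 152.8 Mb or 5.203% of the span. The widest RNA PolII domain reached 258400 bp, and the widest FOXO1 interval 4908 bp. The median gap between neighbouring intervals was 32.6 kb for FOXO1 and 17.6 kb for RNA PolII. Within each list, wider intervals had higher scores, with a Spearman rho across intervals of 0.52 for FOXO1 and 0.62 for RNA PolII.

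The 10 highest-scoring FOXO1 intervals were spread over 7 chromosomes. The highest score, 213, belonged to chromosome 1, 145113577 to 145115548. The intervals at 145082907 to 145084929 and 144988687 to 144990298 of the same chromosome followed with scores of 203 and 188, so that 3 of the 5 highest lay close together; none of the 3 overlapped an RNA PolII domain. Chromosome 6, 58776234 to 58779419, also scored 203. Among sites away from these, chromosome 11, 114049541 to 114050800, scored 191 and stood at the end of a cluster of 8 FOXO1 peaks. Chromosome 2, 227619027 to 227621406, scored 185 and also overlapped RNA PolII. Chromosome 17, 57928827 to 57930133, scored 165 and overlapped RNA PolII and lay in a cluster of 7 FOXO1 peaks. Chromosome 20, 19944801 to 19945906, with 171, and chromosome 3, 143327678 to 143328314, with 166, had no RNA PolII domain over them. Chromosome 1, 121484001 to 121485549, scored 169. Of the 10 intervals, 3 lay within 1 Mb of a span of 2 Mb or more with no interval of either list: those on chromosome 6, at 121484001 of chromosome 1 and at 144988687 of chromosome 1.

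The highest RNA PolII score, 177, fell on chromosome 6, 58773800 to 58779399, the same place as the FOXO1 interval with 203. Chromosome 11, 65264000 to 65279599, followed with 172 and held no FOXO1 peak. Chromosome 1, 121483200 to 121485599, scored 169 and again coincided with a high FOXO1 interval. The next domains were chromosome 20, 35169000 to 35188199 (159), chromosome 5, 148784400 to 148823999 (156), and chromosome 5, 172189600 to 172201199 (148). Both chromosome 5 domains held FOXO1 peaks, 3 and 2 respectively, and the chromosome 20 domain held none. The remaining domains of the first 10, on chromosomes 7, 17, 8 and 19, scored 134, 134, 132 and 118 and held no FOXO1 peak. Leaving out intervals within 1 Mb of long peak-free spans left 25558 FOXO1 intervals and 12890 RNA PolII domains.

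Most FOXO1 sites lay outside RNA PolII domains, but more lay inside them than random placement gave. RNA PolII domains overlapped 2605 of the 26620 FOXO1 peaks, or 9.79% (95% Wilson interval 9.43 to 10.1%), against 5.49% ± 0.14 (SD over 1000 random placements; highest 6.01%). The ratio was 1.78. The other 24015 FOXO1 peaks, 90.2%, touched no domain. Seen from RNA PolII, 1668 of 13460 domains held a FOXO1 peak, or 12.4% (95% Wilson interval 11.85 to 12.96%), against 9.74% ± 0.24 at random (highest 10.6%), a ratio of 1.27. The share of FOXO1 peaks in domains was above the random mean on all 22 autosomes, and above every placement on 19 of them. The ratio ranged from 1.19 on chromosome 17 to 2.58 on chromosome 18. When each FOXO1 peak was moved by 5 to 25 kb instead of being placed anew, the moved peaks overlapped domains in 9.64% on average, and 122 of 1000 such moves gave a share as high as that observed. Seen from RNA PolII, separate moves break up FOXO1 clusters and so reach more domains, which gave ratios of 0.96 after 5 to 25 kb and 0.95 after 20 to 100 kb. With all peaks of a chromosome moved together, which keeps clusters whole, the moved peaks hit 12.5% and 12.1% of domains, ratios of 0.99 and 1.02, and 770 and 127 of 1000 moves gave a share of domains as high as observed. For FOXO1 peaks these joint moves gave 9.66% after 5 to 25 kb (124 of 1000 as high) and 9.07% after 20 to 100 kb (0 of 1000 as high). Neither overlap could thus be told from that after moves of 5 to 25 kb with clusters kept whole; of the peaks in domains, 41.1% on average stayed in the same domain after separate moves of 5 to 25 kb and 9.97% after those of 20 to 100 kb.

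Relative to random placement, FOXO1 peaks were most enriched deep inside RNA PolII domains and were depleted more than 100 kb away from them, although more than 100 kb away is where most FOXO1 peaks lay. Peak midpoints more than 5 kb inside a domain numbered 1242, which was 4.67% of peaks against 1.98% at random, a ratio of 2.36. Between 1 and 5 kb from the edge, inside, the ratio was 1.58, and within 1 kb of the edge, inside, it was 1.47. Only wide domains have positions more than 5 kb from the nearest edge, while the bands nearer the edge also take in narrow domains. Wide domains also held FOXO1 peaks more often relative to random placement, as given below. The bands were not compared within classes of domain width or with moved peaks, so depth was not separated from width. The stretch within 1 kb outside a domain held 172 midpoints, 0.82 times the random number, and only 2 of 1000 placements gave as few. The ratio was above 1 again from 1 to 5 kb (1.24), from 5 to 25 kb (1.36) and from 25 to 100 kb (1.32) outside. More than 100 kb from any domain lay 54.5% of FOXO1 peaks, against 67.5% at random, a ratio of 0.81. The median distance from a FOXO1 midpoint to the nearest domain was 124.2 kb, against 253.8 kb at random (range over placements 242.5 to 264.7 kb). These placements could fall into long peak-free spans. With placements kept out of them, the ratio was 2.15 more than 5 kb inside and 0.85 beyond 100 kb, where the random share was 64.5%. The median distance was not recomputed in this way.

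**Figure D1:**
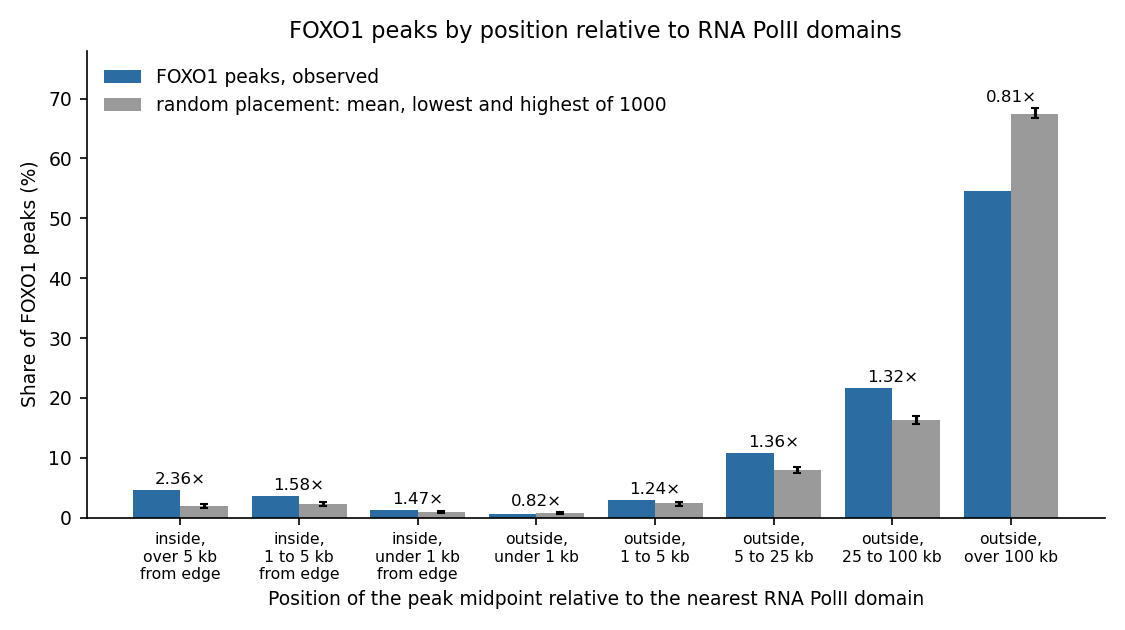
Share of the 26620 FOXO1 peaks (vertical axis, percent) by the position of their midpoint relative to the nearest RNA PolII domain (horizontal axis), with blue bars for the observed share and grey bars for the mean of 1000 random placements, whose lines run from the lowest to the highest placement. The number above each pair is observed over random: it is 2.36 deep inside domains, 0.82 just outside the edge and 0.81 beyond 100 kb. Only wide domains have positions deep inside, so depth and domain width are not separated.

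Wide RNA PolII domains held FOXO1 peaks more often than random placement gave, and narrow ones less often. The domains were split by width into 3 classes of equal number. Of the widest class (11000 to 258400 bp), 25.9% held a FOXO1 peak, against 18.3% at random and at most 19.9% in any placement, a ratio of 1.42. In the middle class 8.34% held one, against 7.39% at random, and 8 of 1000 placements gave as high a share. In the narrowest class (200 to 5200 bp) the share was 2.92% against 3.55% at random, a ratio of 0.82, and 993 of 1000 placements gave as high a share. The deficit in narrow domains did not hold for the intervals with at least 2 times the lowest score of each list, where the ratio was 1.04. Against FOXO1 peaks moved separately by 20 to 100 kb, the ratio was 1.02 in the widest class and 0.67 in the narrowest. Separate moves break up clusters, and joint moves were not run for these classes, so the part due to this is not known.

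FOXO1 peaks with higher scores overlapped RNA PolII more often. The share rose from 6.79% (95% Wilson interval 6.14 to 7.49%) for peaks scoring 9 to 20 to 11.6% (10.8 to 12.5%) for those scoring 48 to 213, while random placement gave 5.28% and 5.62%. The median score was 33 for peaks that overlapped RNA PolII (interquartile range 24 to 46, 2605 peaks) and 30 for the others (22 to 43, 24015 peaks). The difference of 3 had a permutation p of 1.00e-05, the smallest that the resamples can give, which stayed at 1.00e-05 after adjustment over 3 measures. Overlapping peaks were also wider, with a median of 894 bp against 821 bp. With the peaks also split into 3 classes of width, the score difference was 3 in the narrowest class (permutation p = 2.00e-05), 1 in the middle class (permutation p = 0.388) and -1 in the widest class (permutation p = 0.491). These tests exchange single peaks as if they were independent. With scores rotated along the genome instead, which keeps neighbouring peaks together, p was 1.00e-04 over all peaks, the smallest that 10000 rotations can give, and 1.00e-04, 0.400 and 0.505 in the 3 classes; the difference of 4 between the narrowest and the widest class had a rotation p of 6.00e-04. RNA PolII domains that held a FOXO1 peak had a median score of 16, and those without had 11. They were also wider, with a median of 16400 bp against 6800 bp, and random placement, which also hits wide domains more often, gave a score difference of 4.12 on average, with 123 of 1000 placements reaching the observed 5. Within 10 classes of domain width the mean difference was 1.20, against 0.13 at random and at most 0.75 in any placement.

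**Figure D2:**
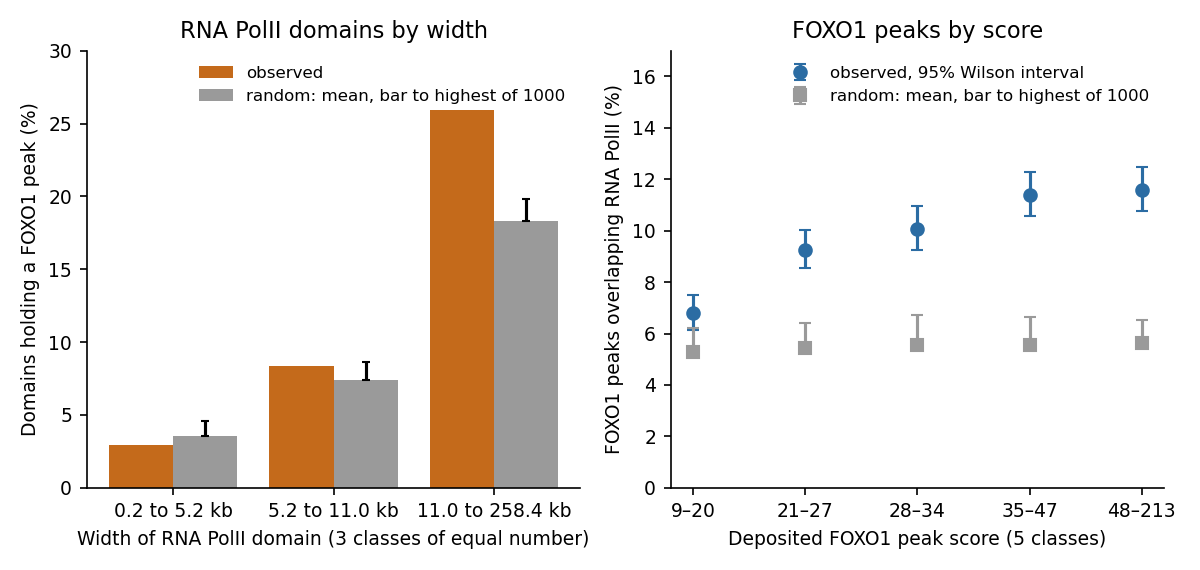
Left, share of RNA PolII domains that hold a FOXO1 peak (percent) in 3 classes of domain width, observed in orange and the mean of random placements in grey, with a line up to the highest of 1000. Right, share of FOXO1 peaks that overlap RNA PolII (percent) in 5 classes of the deposited FOXO1 score, with 95% Wilson intervals in blue and random placements in grey; the share goes from 6.79% in the lowest class to 11.6% in the highest.

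Among the highest-ranking overlapping pairs, some lay in wide RNA PolII domains with more than 1 FOXO1 peak. Others held a single FOXO1 peak in a narrower domain of 1.6 to 13.2 kb. The 10 pairs with the best worse-of-both rank began with the intervals on chromosome 6 at 58776234 and chromosome 1 at 121484001 described above. On chromosome 17 an RNA PolII domain of 24.0 kb (57913800 to 57937799, score 101) held 6 FOXO1 peaks, the strongest of them scoring 165. The fourth pair, on chromosome 7 at 61968811 to 61969601, scored 113 for FOXO1 and 99 for RNA PolII and lay beside a long peak-free span. A domain of 135.8 kb on chromosome 10 (75756800 to 75892599) held 5 FOXO1 peaks, the highest scoring 104. On chromosome 2, the domains at 28612400 to 28655799 and 105961200 to 106017999 held 2 and 6 FOXO1 peaks with top scores of 96 and 95. The pairs on chromosome 7 at 66087000 to 66100199 and chromosome 1 at 145436600 to 145444999 held 1 FOXO1 peak each, scoring 95 and 101. The last pair was on chromosome 8, where a domain of 201.6 kb (30241400 to 30442999) held 16 FOXO1 peaks with a highest score of 145. Of these 10 pairs, 4 lay within 1 Mb of a long peak-free span.

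Domains with many FOXO1 peaks were rare. Of all RNA PolII domains, 58 held 5 or more FOXO1 peaks, and their median width was 81500 bp. The domains with the most were chosen after their values were seen. Chromosome 2, 69239400 to 69493999, a domain of 254.6 kb, held 19 FOXO1 peaks. Chromosome 10, 63738800 to 63865599, 126.8 kb wide with an RNA PolII score of 62, held 18. The chromosome 8 domain named above held 16. Chromosome 2, 36578400 to 36803999, held 14, and chromosome 13, 110906400 to 111133199, held 11.

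FOXO1 peaks were clustered along the chromosomes. Most clusters touched no RNA PolII domain, but clustered peaks overlapped RNA PolII more often than single peaks. There were 165 clusters of at least 5 peaks with a median length of 22.8 kb, against 2.32 on average and at most 8 under random placement, a ratio of 71.2. Placements kept out of long peak-free spans gave at most 10 clusters, a ratio of 48.9. When each peak was moved separately by 20 to 100 kb, 74.7 clusters were counted on average and at most 106, a ratio of 2.21. Neighbouring FOXO1 intervals lay as close as 1 bp apart, so a stretch split by interval calling can count as several peaks. All of these comparisons break up such stretches, and clusters were not recounted with intervals within 1 kb merged. The 165 clusters held 933 peaks, 3.50% of the list. Of these clusters 39, or 23.6%, touched an RNA PolII domain. The share of clusters that would touch a domain at random was not measured. Peaks in the 165 clusters overlapped RNA PolII in 18.1% (95% Wilson interval 15.8 to 20.7%), peaks in runs of 2 to 4 in 10.7% (10.1 to 11.3%) and single peaks in 8.59% (8.15 to 9.05%). Their median scores were 37, 32 and 28. The largest clusters were chosen after their values were seen. The largest of all held 12 peaks over 43.5 kb of chromosome 10 (63776383 to 63819927) and lay wholly in an RNA PolII domain. The next 7 had none over them, among them 11 peaks over 57.7 kb of chromosome 3 (171499225 to 171556928, median score 58) and 10 peaks over 44.3 kb of chromosome 1 (235092578 to 235136909, highest score 122). A cluster of 8 peaks on chromosome 11 (114015781 to 114050800, highest score 191) was covered by RNA PolII over 82.9% of its length.

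**Figure D3:**
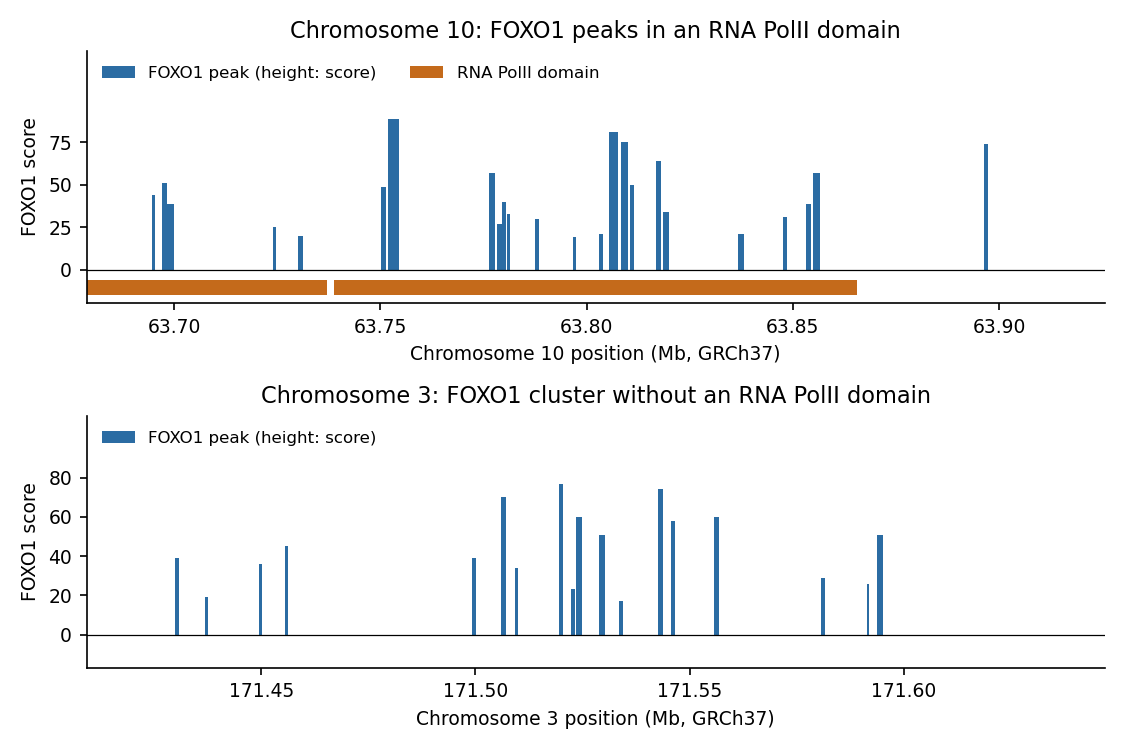
FOXO1 peaks (blue, height is the deposited score) and RNA PolII domains (orange) along 2 regions, with the position in Mb on GRCh37 on the horizontal axis. Above, the chromosome 10 domain with 18 FOXO1 peaks; below, the chromosome 3 cluster of 11 peaks, in a window without any RNA PolII domain.

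The density of FOXO1 peaks differed less between autosomes than that of RNA PolII domains, and the densities did not rise together. Chromosome 19, the most gene-dense human chromosome, had the most RNA PolII domains per Mb (17.2) and the fewest FOXO1 peaks per Mb (5.27) of the 22 autosomes. Chromosome 6 had the most FOXO1 peaks per Mb of span (11.7) with 3.50 RNA PolII domains per Mb. With long peak-free spans left out of the length, chromosomes 21 (14.3) and 9 (12.4) ranked above chromosome 6 (12.3). On chromosome 19, 37.7% of FOXO1 peaks lay in RNA PolII domains, against 20.2% at random; on chromosome 6 it was 6.17% against 3.98%. Across autosomes Pearson's r between the densities was -0.64 (permutation p = 0.00412, adjusted 0.0102 over 7 relations), and Spearman's rho was -0.41 (permutation p = 0.0578, adjusted 0.109). Without chromosomes 19 and 22, which lie farthest from the median RNA PolII density, r was -0.38 (permutation p = 0.104), and without chromosome 19 alone it was -0.35 (permutation p = 0.124). The call was thus not reached without chromosome 19, while r stayed negative.

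**Figure D4:**
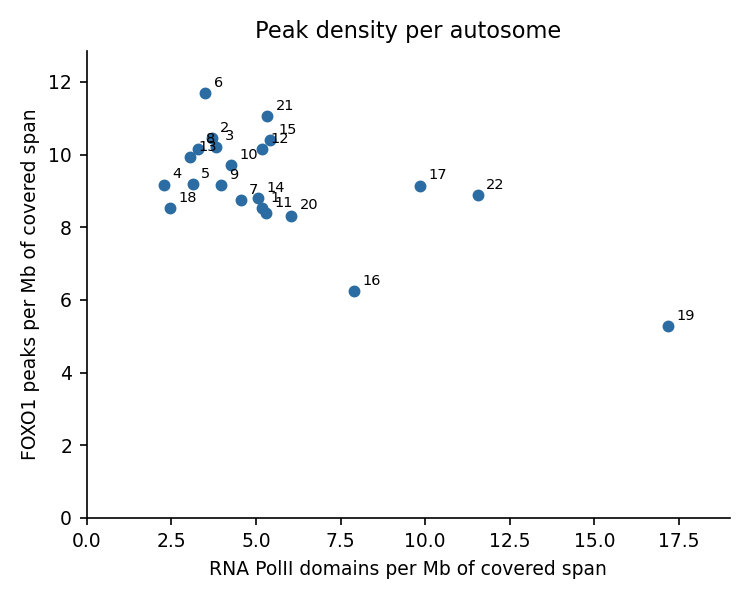
FOXO1 peaks per Mb (vertical axis) against RNA PolII domains per Mb (horizontal axis) for the 22 autosomes, each a point labelled with its number; the length is the span from the first to the last interval. Chromosome 19 sits at 17.2 RNA PolII domains and 5.27 FOXO1 peaks per Mb, apart from the others.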

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

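Of 62 alternative settings of 11 results, 46 left the result unchanged, 7 ended a call and 9 turned its direction. All 16 that changed a result were chosen after seeing the data. A turned direction meant only a value on the other side of no difference, not that an effect in that direction was shown. Among these 9 was the ratio of 0.99 for domains after joint moves of 5 to 25 kb, which 770 of 1000 moves reached. Another was the score difference of -1 in the widest class of peak width (permutation p = 0.491). Unchanged meant the same direction and side of the threshold. For the numbers of intervals, which have no test or direction, it meant only staying within 1.5 times. The number of intervals stayed within 1.5 times under every setting tried (FOXO1 23651 to 26101, RNA PolII 11357 to 13135). The ratio of observed to random overlap of FOXO1 peaks was 1.64 to 1.95 under the alternatives planned before the data were examined and 1.62 with placements kept out of peak-free spans. With FOXO1 peaks moved separately by 5 to 25 kb it was 1.01, and seen from RNA PolII domains 0.96; with 20 to 100 kb the values were 1.08 and 0.95, and in domains of at most 10 kb 0.82 for both. The values below 1 over all domains came with broken-up clusters: with all peaks of a chromosome moved together they were 0.99 and 1.02, within the range of the moves, and for FOXO1 peaks 1.01 and 1.08; in domains of at most 10 kb 0.82 and 0.85 stayed below every move. The observed score difference of 3 lay outside the -1 to 2 that scores rotated along the genome gave; it was 1 in the middle and -1 in the widest class of peak width. The ratio in the narrowest class of domains was 1.04 with the higher score minimum, and in the widest class it was 1.02 with peaks moved separately by 20 to 100 kb. Across autosomes r was -0.38 without the 2 farthest chromosomes and -0.35 without chromosome 19. The cause of the changes with score minimum and peak width was not tested. The 165 FOXO1 clusters compare with at most 106 after moves of 20 to 100 kb, a ratio of 2.21 to their mean, and with 38 and 754 clusters when peaks had to lie within 5 or 25 kb. Clusters of merged intervals were not counted. No paired analysis was possible because each antibody has 1 library and the results come from no test between samples. Not run were the alternatives that need genes, sequence, p-values or a placement inside genes. Read depth is unknown, so an interval missing from a list does not show that the factor was absent there.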

Other observations

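At the scale of 1 Mb, FOXO1 and RNA PolII went together within chromosomes although they did not between them. Bins of the 22 autosomes with no RNA PolII held 7.34 FOXO1 peaks on average (695 bins), those with RNA PolII over less than 5% of their length held 10.6 (959 bins), and those with 15 to 30% held 12.6 (250 bins). The 74 bins with 30% or more held 11.0. Spearman's rho across 2552 bins was 0.26, and within single autosomes it ranged from 0.15 to 0.62 and was positive on all 22; neighbouring bins are not independent, so no p is given. The 2552 bins do not take in the whole span of the autosomes, and the rule for leaving bins out is not given here. The effect of the choice of bins on rho was not tested.

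The following tests were all added after seeing the data. They were also chosen or worded after their own results were partly seen, except those without the highest scores, in short domains, with the covered share and without chromosome 19.

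The excess of FOXO1 peaks in RNA PolII domains may have several sources. Long peak-free spans, which only lower the random share, are argued against as the whole cause: with placements kept out of them the ratio was 1.62. Without the highest-scoring 1% of each list the ratio was 1.75, so the excess did not rest on those intervals. This cannot decide whether loci that attract reads in any library add to it. The part left out was small, a high score does not identify such loci, and the input was not analysed. Most of the excess went with the region within 20 to 100 kb, since peaks moved that far still overlapped domains in 9.06% against 5.49% at random. After moves of 100 to 500 kb it was 7.07% (ratio 1.38). Counted on FOXO1 peaks, the remainder is argued against as regional at 20 to 100 kb. There, 9.79% was above all of 1000 moves (ratio 1.08), also with the peaks of a chromosome moved together. Counted on RNA PolII domains, no such remainder was seen. The ratio was 0.95 with separate moves and 1.02 with joint moves, and 127 of 1000 joint moves gave a share as high. For domains of at most 10 kb neither prediction was met, a share within or above the range of the moves: it was below all of them (0.82), so no preference for short domains was seen; shared regions on a finer scale also stay open, since moves of 5 to 25 kb gave 9.64%, and no biological explanation was tested.

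Whether the strongest intervals of both antibodies are in part technical cannot be told. The highest RNA PolII interval and one of the highest FOXO1 intervals fell on the same place of chromosome 6, and both lists had high intervals at position 121484001 of chromosome 1 and beside a span on chromosome 7. Of the 20 highest FOXO1 intervals, 4 lay within 1 Mb of a peak-free span of 2 Mb or more. This was 20% against 3.99% of all FOXO1 intervals, a ratio of 5.01. Of the 100 highest FOXO1 intervals only 7 did, or 7%, so the size of the ratio depends on the cut-off. For RNA PolII it was 3 of the 20 highest against 4.23% of all. The ratio of 5.01 restates the pattern. Of the 4 FOXO1 intervals beside spans 2 overlapped RNA PolII, against 3 of the other 16 (Fisher exact p = 0.249). These are too few to decide whether reads pile up beside assembly gaps in any library. Input values are not analysed here, and no biological explanation was tested.

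The negative r between the densities across autosomes is unlikely to come from how the caller split RNA PolII intervals. It was -0.63 with the covered share in place of the number (bootstrap interval -0.85 to -0.16). Without chromosomes 19 and 22 the covered share gave -0.40 (permutation p = 0.0884, adjusted 0.121), so the call was not reached there. FOXO1 density was lowest on chromosomes 19 and 16 (5.27 and 6.23 per Mb). Chromosomes 22 and 17, with more RNA PolII domains per Mb than chromosome 16, had 8.88 and 9.14. Whether chromosome 19 alone sets the relation cannot be told apart from a general trend: r was -0.35 without it, with a bootstrap interval of -0.66 to -0.0038 over 21 autosomes. Base composition, which differs between these chromosomes, was not tested because no sequence was used here.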
